A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

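Gene expression was measured in *Saccharomyces cerevisiae* with Affymetrix Yeast Genome S98 arrays, on which each probe set is a group of short probes against one transcript. A wild-type strain (Y255) and an isogenic strain lacking CBC2 (Y2685) were each measured on 3 arrays, one per sample, 6 in all. Per the labels, cells were grown in synthetic complete medium at 30 °C to an OD600 of 1, and total RNA was extracted with glass beads and phenol. The design text calls the experiments independent, but the labels do not say that the samples came from separate cultures, so the p-values measure the spread between these samples, part of which may be technical.

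The deposited values are linear intensities, 1 per probe set and array for 9335 probe sets, never below 0. The summarisation software and any scaling by the authors are not given in the sources used here. The trimmed mean of the deposited intensities (2% trimmed at each end) was 393.5, 473.9 and 301.5 on the wild-type arrays and 440.7, 378.3 and 251.7 on the deletion arrays, a 1.88-fold range. The rule set before the data were examined asked for quantile normalisation where this range passed 1.2-fold, so the intensities were quantile normalised, which gives every array one distribution and can hide a change of the whole messenger RNA pool. Values under the 10th percentile (a normalised intensity of 8.25) were raised to that floor and log2 transformed. A gene at the floor on all arrays of a strain has only a bound there, and its fold is written as at least N-fold. The run information files of the arrays, deposited per sample, were read only for the fluidics station and module, the hybridisation and scan batches and the order of scanning.

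The 60 Affymetrix control probe sets and the dimmest 25% of the others by mean log2 value were left out, and 6956 probe sets were tested. The strains were compared over all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all tested probe sets. Every adjusted p of a gene below is limma's, and a probe set or gene was called at an adjusted p under 0.05. Log2 fold changes are deletion minus wild type, with their standard errors (SE). Intensities are means ± SD over 3 arrays of normalised, floored values. The number of arrays limits the precision: the median SE of a tested probe set was 0.20 on the log2 scale. On data simulated for this comparison, over 6956 probe sets, the test recovered 9.1% of simulated changes of 0.5 on the log2 scale, 53.7% of changes of 1 and 94.0% of changes of 2, and 2.8% of its 108 calls were false. Only 66, 67 and 67 probe sets were changed by these sizes, and noise was drawn independently for each probe set. The adjustment depends on how many probe sets change. With far more called in the real comparison, these rates do not give its power.

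Probe sets were named through a platform annotation table, which gave 6504 probe sets 1 gene symbol, 328 several and 2503 none. All 6504 were matched by gene ID to a gene table of assembly R64, used for names, gene classes, lengths and gene order. Probe sets with several symbols or none were counted but not named. A gene was represented by its brightest probe set without a cross-hybridisation suffix, or of any suffix where it had no other, which gave 5257 tested genes, 5068 of them from such a plain probe set. Of 98 genes with several plain tested probe sets, 1 had probe sets called in opposite directions.

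Before the data were examined, 34 gene lists were fixed, of which 3 were not run: ribosomal proteins with introns, telomere-proximal genes and retrotransposons, which needed annotation not used here. The intron-containing genes were taken from a list written by hand. Lists with at least 5 tested members, 30 in all, were tested with limma's camera (preset inter-gene correlation of 0.01), with Benjamini-Hochberg adjustment over the lists, then with the correlation estimated from the data and with fry. Another 3 lists (small nucleolar and nuclear RNA genes, transfer RNA genes, and allantoin and nitrogen catabolite genes) were added after the values had been seen. The named genes follow a rule fixed in advance: CBC2, its partner STO1 and the genes next to CBC2; the 12 largest rises and 12 largest falls among called genes with a plain probe set whose strains did not overlap; and up to 4 members of smallest p from each list. Genes outside the rule are said to be so where they appear.

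The alternatives were the deposited scale, scaling to one median, another floor, a pseudocount, other filters on dim probe sets, other variance models, a 2-fold requirement, the replicate number and the scan day as blocks, array weights, leaving out each array in turn, counting by gene, and the 2 other list tests. The fluidics station as a block was added after the files had been read, and the ribosomal protein list without RPP1, the cap-binding list without CBC2 and the adjustment of the added lists together with the fixed ones after the values had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.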

Results

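Transcript levels were measured in a wild-type budding yeast strain and in an isogenic strain without CBC2, which encodes the small subunit of the nuclear cap-binding complex, the pair of proteins that binds the 5′ cap of new RNA polymerase II transcripts. Each strain was measured on 3 arrays. The comparison asks which transcripts differ in level when this subunit is missing. Correlations between arrays over all probe sets other than controls (log2 values) were 0.980 to 0.988 within a strain and 0.951 to 0.969 between strains, and the first principal component, with 65.9% of the variance, placed the 3 deletion arrays apart from the 3 wild-type arrays. The ratio of 3′ to 5′ signal, a measure of RNA integrity, was 1.15 to 1.47 for ACT1 on the wild-type arrays and 1.02 to 1.42 on the deletion arrays. For the TATA-binding protein gene it was 2.48 to 3.74 and 3.67 to 5.13.

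CBC2 (YPL178W) was checked first. Its normalised intensity was 828 ± 60.6 (SD, n = 3) in the wild type and at the floor of 8.25 on each of the 3 deletion arrays, where the deposited values were 1.9, 2 and 4.5. The gene was at least 100-fold lower in the deletion strain (log2 fold change -6.65, SE 0.17, adjusted p = 1.18e-08). STO1 (YMR125W), which encodes the large subunit of the same complex, rose from 180 ± 8.49 to 271 ± 16.4 (n = 3 each; log2 fold change 0.59, SE 0.15, adjusted p = 0.0169). The STO1 call was lost on the deposited scale (log2 fold change 0.27, adjusted p = 0.732), with the fluidics station as a block (0.65, adjusted p = 0.0968) and without wild-type replicate 3 (0.55, adjusted p = 0.0546).

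The strains differed widely. Of 6956 probe sets tested, 2187 were called (31.4%), 1058 higher and 1129 lower in the deletion strain, and 745 of them changed at least 2-fold, 368 up and 377 down. Counted by gene, 1715 of 5257 were called, 857 higher and 858 lower. The values of the strains did not overlap for 47.4% of the tested probe sets, against the 10% that chance gives with 3 against 3. On the deposited scale, where the median log2 change of all tested probe sets was -0.27 instead of -0.01, only 728 probe sets were called, 165 higher and 563 lower. Wild-type replicates 1 and 2 were washed on one fluidics station and the other 4 arrays on a second. With the station as a block, a fit in which wild-type replicate 3 alone stands for the wild type within the second station, 675 probe sets were called, 334 higher and 341 lower. Deletion replicate 2 was hybridised and scanned apart from the other arrays, and without it 1861 probe sets were called.

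Among the 12 genes with the largest rises, 5 encode small RNAs. The small nucleolar RNA gene SNR63 went from 22.9 ± 0.98 to 220 ± 36.6 (n = 3 each; log2 fold change 3.25, SE 0.20, adjusted p = 1.84e-05). SNR128, SNR11 and SNR13, of the same class, rose by 3.05, 3.01 and 2.32 on the log2 scale, and SNR6, the U6 spliceosomal RNA, by 2.93. The other risers were DPI8 (3.10), YOR387C (2.93), the hexose transporter gene HXT2 (2.92), the glycerophosphoinositol permease gene GIT1 (2.67), the S-methylmethionine permease gene MMP1 (2.46), TMA10 (2.31) and ANB1 (2.29), which encodes a form of translation factor eIF5A made under low oxygen. YOR387C has a near-identical copy elsewhere in the genome, so its value is uncertain. After CBC2, the largest falls were YGR035C (-2.95), the serine and threonine deaminase gene CHA1 (-2.87), YJL213W (-2.47), the vitamin B6 synthesis genes SNO1 (-2.35) and SNZ1 (-2.24), the spore-forming genes ADY3 (-2.21) and SPO21 (-2.08), the histone deacetylase gene HOS2 (-2.13), the allantoate permease gene DAL5 (-2.08), the allantoinase gene DAL1 (-2.06) and the cell fusion gene PRM1 (-1.999). Each of these 24 genes passed the test (adjusted p from 1.18e-08 to 0.00942), and HOS2 alone among them lost its call in a setting that tested it, without the filter on dim probe sets (-2.13, adjusted p = 0.0763) and with the station block (-2.31, adjusted p = 0.0833).

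**Figure D1:**
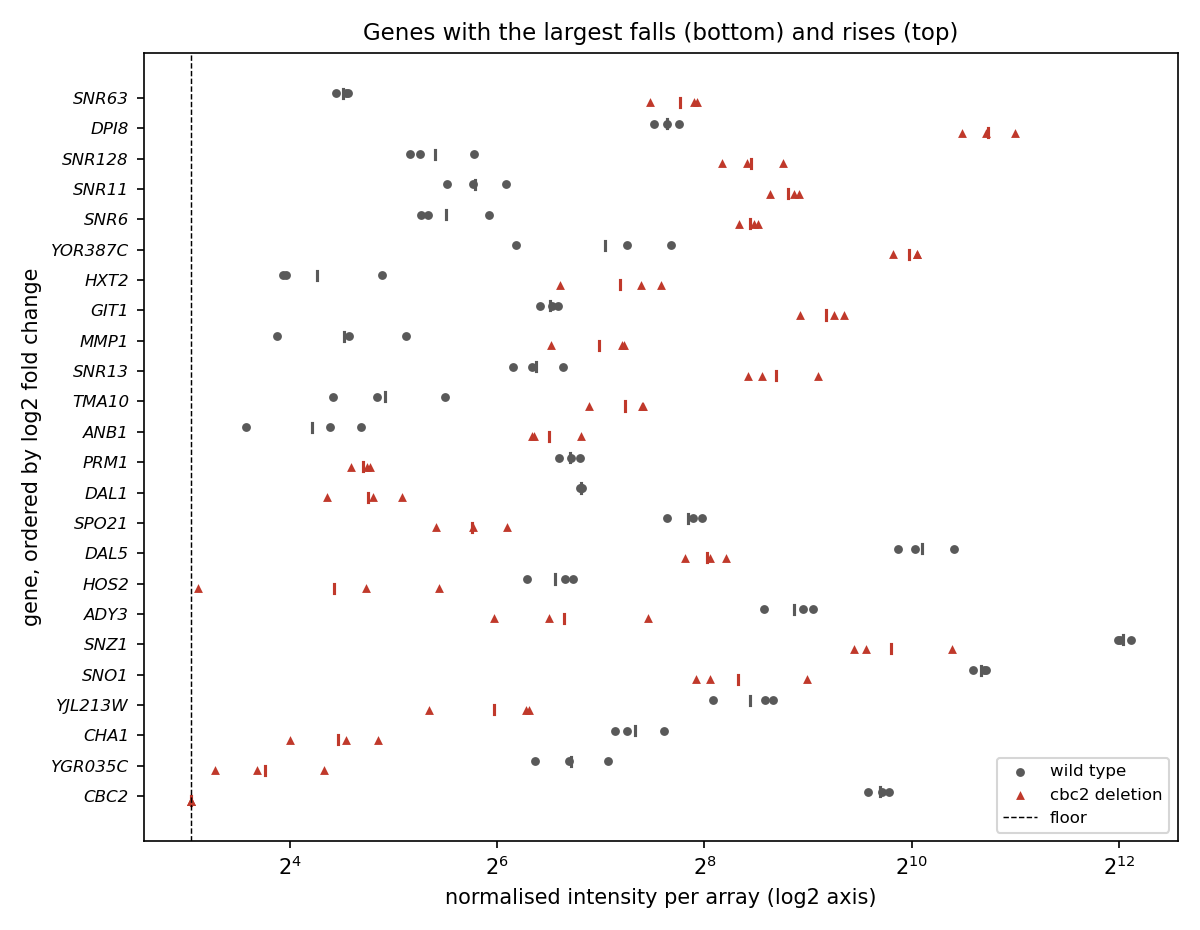
Normalised intensity per array (log2 axis) of the 12 genes with the largest rises and the 12 with the largest falls in the cbc2 deletion strain. Circles are the 3 wild-type arrays, triangles the 3 deletion arrays, short bars the means of the log2 values and the dashed line the floor of 8.25. The strains do not overlap for any of these genes, and CBC2 lies at the floor on all 3 deletion arrays.

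Among genes of protein synthesis, more rose than fell in the deletion strain. Of 81 genes of the ribosomal protein list, 55 rose, 1 fell and 25 were not called (62 called when adjusted over the list alone), with a median log2 change of 0.69. The fixed rule for its symbols also took in RPP1, which encodes a subunit of RNase P and was not called. Without it the list held 80 genes, 24 of them not called, at the same median of 0.69. RPS7A went from 1470 ± 285 to 4887 ± 525 (n = 3 each; log2 fold change 1.75, SE 0.17, adjusted p = 0.000202) and RPL38 rose by 1.57, while RPS22B, named after its value was seen, fell by 1.12 on the log2 scale. Of 24 translation initiation factor genes, 13 rose and none fell (median 0.59, 17 called when adjusted over the list alone). NIP1, a subunit of eIF3, rose by 1.15 and TIF4631, a form of eIF4G, by 0.96. Of 75 ribosome biogenesis genes, 25 rose, 1 fell and 49 were not called (median 0.44, 27 when adjusted over the list alone), among them GAR1 (1.38), a protein of the small nucleolar particles that guide pseudouridine formation, and the helicase gene DBP3 (1.07). The camera test called all 3 lists (adjusted p = 7.44e-17, 4.59e-05 and 4.60e-05). With an estimated correlation 0 of the 30 lists were called by camera (6 at an unadjusted p under 0.05), these 3 included (adjusted p = 0.152, 0.152 and 0.352). Correlation between genes is not the only reason, as this form of the test weakened uncorrelated lists too. For the phosphate regulon the estimate was -0.04, under the preset 0.01, yet the unadjusted camera p went from 2.82e-05 to 0.0106.

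Among phosphate, hexose transport, respiration and proteasome genes, more rose than fell, and most respiration and proteasome genes were not called. Of 18 genes of the phosphate regulon, 11 rose and 3 fell (median 0.84, 16 called when adjusted over the list alone). The acid phosphatase gene PHO5 went from 1501 ± 145 to 6410 ± 68.9 (n = 3 each; log2 fold change 2.10, SE 0.13, adjusted p = 1.81e-05), and VTC3, of the polyphosphate synthesis complex, rose by 1.79. Of 10 hexose transport genes, 4 rose, 1 fell and 5 were not called (median 0.27, 5 when adjusted over the list alone): besides HXT2, HXT4 rose by 2.14, HXT6 by 1.91 and HXT7 by 1.81, the last 2 being near-identical copies that their probe sets do not separate. Of 48 respiration and tricarboxylic acid cycle genes, 16 rose, 2 fell and 30 were not called (median 0.28, 18 when adjusted over the list alone). SDH2 rose by 1.06 and FUM1 by 1.09, and NDE1, an external NADH dehydrogenase gene, fell by 0.83. Of 32 proteasome genes, 11 rose, none fell and 21 were not called (median 0.32, 12 when adjusted over the list alone), among them PRE6 (1.15) and RPN10 (1.10). The camera adjusted p was 0.000121 for phosphate, 0.0403 for hexose transport, 0.0093 for respiration and 0.000995 for the proteasome, and with an estimated correlation it was 0.152, 0.235, 0.152 and 0.233. The hexose transport call was also lost with the dimmest 50% of probe sets left out (median 0.05, adjusted p = 0.361), without the filter on dim probe sets (median 0.23, adjusted p = 0.13), with the fluidics station as a block (median 0.34, adjusted p = 0.056), and with the scan day as a block or without deletion replicate 2 (median 0.17, adjusted p = 0.0512 in both).

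Among genes of iron uptake and of purine, sterol and amino acid synthesis, more fell than rose in the deletion strain. Of 23 genes of the iron regulon, 15 fell and 1 rose (median -0.75, 17 called when adjusted over the list alone). ENB1, an enterobactin transporter gene, went from 1465 ± 205 to 378 ± 77.5 (n = 3 each; log2 fold change -1.96, SE 0.19, adjusted p = 0.000188), and the ferric reductase gene FRE2 fell by 1.87. Of 15 purine synthesis genes, 8 fell and 2 rose (median -0.64, 13 when adjusted over the list alone). ADE2, ADE1 and ADE8 fell by 1.95, 1.44 and 1.22, and IMD2, which encodes an IMP dehydrogenase of the guanine branch, rose by 1.65. IMD2 was read from a probe set with a cross-hybridisation suffix, so its value may include related transcripts. Of 24 ergosterol genes, 12 fell and 1 rose (median -0.52, 17 when adjusted over the list alone), with ERG3 at -1.15 and HMG1 at -0.89. Of 43 Gcn4 targets of amino acid synthesis, 17 fell, none rose and 26 were not called (median -0.36, 19 when adjusted over the list alone). HIS3 fell by 1.74 and ARO1 by 0.71, and SNZ1 and SNO1 of the same list are given above. The camera adjusted p was 4.70e-05 for iron, 0.00519 for purine, 4.60e-05 for ergosterol and 4.59e-05 for the Gcn4 targets, and with an estimated correlation it was 0.330, 0.239, 0.152 and 0.330. With the arrays scaled to one median the Gcn4 list was no longer called (median -0.01, adjusted p = 0.199).

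Among pheromone response, auxotrophic marker, heat shock and Yap1 target genes, more fell than rose, and at least as many were not called. Of 17 pheromone response genes, 8 fell, none rose and 9 were not called (median -0.65, 9 called when adjusted over the list alone). PRM1, FIG2 (-1.70), PRM10 (-1.49) and the agglutinin subunit gene AGA1 (-1.35) had the smallest p of these. Of 8 auxotrophic marker genes, 4 fell (median -0.69, 5 when adjusted over the list alone): ADE2 and HIS3, which other lists also hold, the arginine permease gene CAN1 (-1.84) and TRP1 (-0.96). Of 22 heat shock chaperone genes, 9 fell, 2 rose and 11 were not called (median -0.37, 12 when adjusted over the list alone), with SSA4 at -1.25 and SSE2 at -0.89 against HSP30 at 1.00. Of 22 Yap1 targets of oxidative stress, 7 fell, none rose and 15 were not called (median -0.23, 7 when adjusted over the list alone), with the drug transporter gene ATR1 at -1.60 and the glutathione transferase gene GTT2 at -1.50. The camera adjusted p was 0.00148 for pheromone response, 0.00148 for the markers, 0.0127 for heat shock and 0.0403 for the Yap1 targets, and with an estimated correlation it was 0.330, 0.152, 0.233 and 0.352. On the deposited scale the heat shock and Yap1 lists were not called (medians -0.38 and -0.38, adjusted p = 0.362 and 0.118), nor with the arrays scaled to one median (medians -0.06 and -0.06, adjusted p = 0.368 and 0.199) or with the fluidics station as a block (medians -0.26 and -0.19, adjusted p = 0.118 and 0.162). The Yap1 call was also lost without wild-type replicate 1 (median -0.18, adjusted p = 0.073) or deletion replicate 1 (median -0.11, adjusted p = 0.0683), and the pheromone call with the dimmest 50% of probe sets left out (median -0.45, adjusted p = 0.11).

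**Figure D2:**
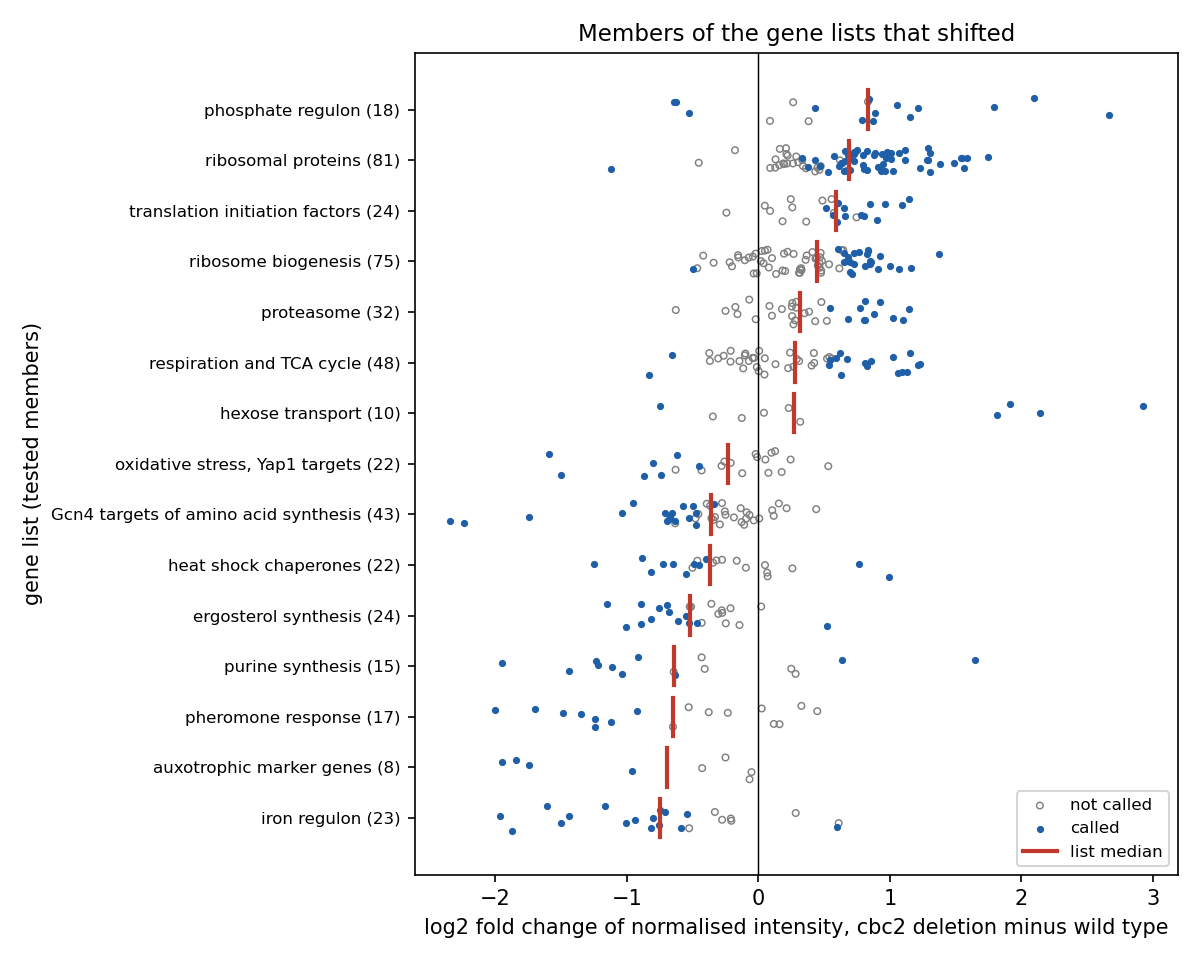
Log2 fold changes (cbc2 deletion minus wild type) of the tested members of the 15 gene lists that camera called; each point is a gene, filled where it was called, the bar is the list median and the number of tested members stands in brackets. List medians run from -0.75 for the iron regulon to 0.84 for the phosphate regulon, and several lists hold members on both sides of 0.

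Camera, which compares the genes of a list with all other genes, called none of the lists closest to the cap-binding complex. The fry test, which asks whether a list moves at all, called the complex and its partners (fry adjusted p = 0.0015 with the deleted gene CBC2 in the list, and 0.00891 for the other 13 genes, which camera did not call, adjusted p = 0.182), splicing factors (0.0098), nonsense-mediated decay (0.0164) and mRNA cleavage, polyadenylation and export (0.023), and not the intron-containing genes (0.218) or the nuclear exosome (0.139). Of 14 genes of the complex and its partners, 6 rose and 2 fell, CBC2 included (9 when adjusted over the list alone, camera adjusted p = 0.549). Their median was 0.21 and their mean, pulled down by CBC2, -0.21. The cap-binding translation factor gene CDC33, named after its value was seen, rose by 1.10, the shuttling RNA-binding protein gene NPL3 by 1.05, and LUC7, of the U1 particle, fell by 0.96. Of 76 intron-containing genes other than ribosomal protein genes, 12 rose and 16 fell (29 when adjusted over the list alone, camera adjusted p = 0.967). Their median was 0.02 and their mean -0.03, and the test pointed down. IWR1 fell by 1.61, CIN2 by 1.59 and SPT14 by 1.29. Of 51 splicing factor genes, 1 rose and 7 fell (median -0.06, 6 when adjusted over the list alone, camera adjusted p = 0.261), with PRP4 at -1.13. Of 30 genes of mRNA cleavage, polyadenylation and export, 5 rose and 2 fell (median 0.17, 7 when adjusted over the list alone, camera adjusted p = 0.261). Of 21 nuclear exosome genes, 1 rose and 1 fell (median 0.07, 0 when adjusted over the list alone, camera adjusted p = 0.699). Of 13 nonsense-mediated decay factors and sensitive transcripts, 4 fell and none rose (median -0.20, 4 when adjusted over the list alone, camera adjusted p = 0.211), among them the telomere maintenance genes STN1 (-1.14) and EST3 (-1.11).

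Of the 5 genes next to CBC2 fixed in advance, PTR2, which the gene table places on another chromosome, rose by 1.00. CUP9 was at -0.53 (adjusted p = 0.0439), TRE1 at -0.52 (adjusted p = 0.0368), TCO89 at -0.46 (adjusted p = 0.0538) and PPQ1 at -0.31 (adjusted p = 0.14). The calls of CUP9 and TRE1 were each lost in 12 of 19 other settings, among them most of those that left out an array (log2 fold changes from -0.35 to -0.70 and from -0.40 to -0.72 where the call was lost), and TCO89 gained a call in 3 (adjusted p from 0.0449 to 0.0476). The list itself, PTR2 included, was not called (median -0.46, mean -0.17, 4 when adjusted over the list alone, camera adjusted p = 0.352). PTR2 pulled its mean up. Without PTR2 the list would have had under 5 members and was not tested, so this result does not speak for the true neighbours alone.

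The remaining lists were not called by camera. By fry, 4 of them were: G1 and S phase (fry adjusted p = 0.0015), sulfur amino acid (0.0094), cell wall integrity (0.0145) and DNA damage (0.0495) genes. Of 26 glycolysis and fermentation genes, 5 rose and 2 fell (median 0.03, 7 when adjusted over the list alone, adjusted p = 0.553), with the hexokinase gene HXK1 at 1.54 and ADH4 at 1.30. Of 20 sulfur amino acid genes, 7 rose and 1 fell (median 0.06, 8 when adjusted over the list alone, adjusted p = 0.151), with MET14 at 2.12 and the sulfate permease gene SUL1 at 2.10. Both lists were called on the deposited scale (medians 0.01 and 0.06, adjusted p = 0.0365 and 0.00467) and with the arrays scaled to one median (medians 0.33 and 0.38, adjusted p = 0.0178 and 0.0116). Of 45 genes that environmental stress induces, 7 rose and 9 fell (median -0.09, mean 0.01, test down, 17 when adjusted over the list alone, adjusted p = 0.614). Of 18 cell cycle genes of G1 and S phase, 7 rose and 3 fell (median 0.26, 11 when adjusted over the list alone, adjusted p = 0.261), with RFA1 at 1.65 and the cyclin gene PCL1 at -1.51. Of 14 DNA damage genes, 5 rose and none fell (median 0.09, 8 when adjusted over the list alone, adjusted p = 0.352), with RNR2 at 1.02. Of 21 cell wall integrity genes, 2 fell (median -0.12, 2 when adjusted over the list alone, adjusted p = 0.229). Of 6 sporulation genes, 2 fell (median -0.19, 2 when adjusted over the list alone, adjusted p = 0.553), IME2 and SPS100. Of 6 haploid cell type genes, 1 fell (median 0.04, mean -0.07, 3 when adjusted over the list alone, adjusted p = 0.862). Of genes named after their values were seen, the alpha-factor gene MF(ALPHA)1 stood at 8353 ± 297 in the wild type and 8064 ± 151 in the deletion strain (n = 3 each; adjusted p = 0.735), while the alpha-factor receptor gene STE2 (26.5 ± 2.71 and 15.8 ± 3.96) was among the dim probe sets left out of the test. Of 4 tested histone genes, too few for a list test, HTB2 rose by 0.75 and HTZ1 by 1.32, and HTB1 (0.30) and HHO1 (0.64) were not called. HHO1 was called without deletion replicate 3 (0.96, adjusted p = 0.00371) and with array weights (0.83, adjusted p = 0.0117), and HTB1 with the arrays scaled to one median (0.58, adjusted p = 0.0258).

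Of the genes named above from lists, some lost their call in a setting. On the deposited scale the median SE of a tested probe set was 0.41 on the log2 scale, against 0.20, and calls were lost with log2 fold changes of 0.85 for NIP1, 0.66 for TIF4631, 0.77 for DBP3, 0.92 for SDH2, 0.93 for FUM1, -0.81 for NDE1, 1.01 for PRE6, 0.87 for RPN10, -0.85 for HMG1, -0.59 for ARO1, -1.06 for SSE2, 0.76 for HSP30, 0.87 for NPL3, 0.89 for CDC33, 0.68 for PTR2, 0.85 for RNR2, 0.64 for HTB2 and 1.08 for HTZ1. HMG1 (-0.53) and ARO1 (-0.26) also lost it with the arrays scaled to one median, and CDC33 (1.10) without the filter on dim probe sets. With the fluidics station as a block the median SE was 0.28, and calls were lost with 0.92 for TIF4631, 1.21 for GAR1, 0.99 for DBP3, 1.09 for RPN10, -0.85 for TRP1, -0.76 for STN1, 0.78 for PTR2, 0.67 for RNR2, -1.02 for IME2, -1.28 for SPS100 and 0.58 for HTB2. IME2 (-0.92) also lost it without wild-type replicate 3, and SPS100 without the filter on dim probe sets (-1.08) or without wild-type replicate 2 (-0.88), wild-type replicate 3 (-0.99) or deletion replicate 3 (-0.89).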

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

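The tests of transfer RNA genes, of the fluidics station and of other splits of the arrays were chosen only after the results had been seen, as were the added gene lists, so the class of small nucleolar and nuclear RNA genes was itself chosen from its values. The other tests of this part were written down before their own outcomes were known.

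Several control probe sets outside the comparison were brighter on every deletion array than on any wild-type array. Probe sets for ribosomal RNA stood out: AFFX-18srRnae_at differed by 4.22 on the log2 scale (25.9 ± 5.35 against 719 ± 801, SD, n = 3), AFFX-25srRnae_at by 3.27, AFFX-18srRnad_at by 2.66 and AFFX-18srRnac_at by 1.84. Of the other probe sets for the large ribosomal RNA, AFFX-25srRnad_at differed by 0.64, AFFX-25srRnab_at by 0.21 and AFFX-25srRnac_at by -0.06, and AFFX-25srRnaa_at was lower, at -1.95. Most control probe sets of bacterial or phage sequence with signal clearly above the floor had a higher mean on the deletion arrays, by unlike amounts. Many of them overlapped between the strains, and deletion replicate 3 was often the highest array. AFFX-DapX-5_at and AFFX-PheX-3_at, both dim, differed most, by 1.22 and 1.12 (from 17.2 ± 7.84 to 39.4 ± 16.04 and from 11.6 ± 1.36 to 26.3 ± 9.83). AFFX-DapX-M_at and AFFX-DapX-3_at differed by 0.75 and 0.72. AFFX-ThrX-M_at, AFFX-ThrX-3_at and AFFX-LysX-3_at, whose strains overlapped, differed by 0.57, 0.49 and 0.45. AFFX-LysX-3_at was at 21.4, 15.2 and 52.8 on the deletion arrays against 18.8, 17.3 and 20.5 on the wild-type arrays. The BioB, BioC and BioDn probe sets ending in _at differed by 0.19 to 0.41. Of these, only AFFX-BioC-3_at and AFFX-BioDn-3_at were higher on every deletion array than on any wild-type array. AFFX-CreX-3_at (0.002) and AFFX-CreX-5_at (-0.19) did not rise. AFFX-PheX-5_at (0.12), AFFX-ThrX-5_at (0.08) and AFFX-LysX-5_at (-0.18) lay at the floor on most arrays, which holds their differences near 0.

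Of 44 tested small nucleolar and nuclear RNA genes, 32 rose and none fell (median log2 change 1.21, 33 when adjusted over the list alone, camera adjusted p = 4.81e-12 over the 30 fixed and 3 added lists). With an estimated correlation the adjusted p was 0.0204 over the 3 added lists alone and 0.126 over all 33, so over all 33 the call is lost. Normalisation between arrays does not account for it, as the lowest median under the other scalings was 0.90. Nor does probe set brightness: the central 95% of random lists matched on mean signal reached 0.18. The shortest 5% of coding genes, of up to 369 bases, had a median of 0.21. That comparison was not matched to the lengths of the small RNAs, so it does not decide short length for them. A candidate explanation that stays open is a larger carry-over of RNA without long poly(A) tails into the labelled sample. Of 77 tested transfer RNA genes, 32 rose, none fell and 45 were not called (median 0.66). The camera adjusted p was 5.39e-09 over all 33 lists, and 0.288 with an estimated correlation. A bootstrap 95% interval of this median, 0.57 to 0.77, spans 0.5 times the class median and lies under the class median itself. It resampled genes as if independent (estimated correlation 0.22). It leaves out the spread between arrays, so it cannot decide. The ribosomal RNA probe sets above were mostly higher and 1 was clearly lower, which does not settle it. An effect of the missing subunit on these RNAs stays open beside it, untested.

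Ribosomal protein genes had a median log2 change of 0.69. Between-array normalisation does not account for it, with 0.69 as the lowest median under the other scalings, nor does length or brightness. The central 95% of random lists ran from -0.09 to 0.21 when matched on gene length and from -0.27 to -0.035 when matched on mean signal. Genes as bright as these thus tended to be lower, and the lists called lower were not tested for brightness. The list was also higher with the fluidics station as a block (median 0.61). What stays open is a difference shared by the arrays of a strain, such as growth at harvest or the order of scanning, in which all wild-type arrays came first, and the strain itself, which may act on these genes; with an estimated correlation the list was not called (adjusted p = 0.152).

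The count of 2187 called probe sets came from the only split of the 6 arrays that parts the strains. The highest of the other splits gave 0 with limma (at most 230 at an unadjusted p under 0.05, against 3014). Each other split puts arrays of both strains in each group, so the strain difference widens the spread within groups. Low counts there follow from that and are not a measure of what chance gives. With 10 splits no share under 0.05 can be had (1 of 10 gave as many). The fluidics station, shared by wild-type replicate 3 and the deletion arrays, does not account for most of it. Over the called probe sets, the difference of that array from the other wild-type arrays had a slope of 0.038 on the difference of the deletion arrays. Those calls counted that array as wild type, which favours a low slope. Over the 1605 probe sets called without it the slope was 0.08, where a station effect would need 0.5 or more. Wild-type replicates 1 and 2 put in its place gave 0.11 and 0.04.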

How the results depend on the processing

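The station block, the ribosomal protein list without RPP1, the cap-binding list without CBC2 and the adjustment of the added lists together with the fixed ones were chosen after the data had been seen; the other settings were set before. Each of these 3 list settings left 15 of the 30 fixed lists called. The count of 2187 called probe sets (1058 higher, 1129 lower) moved by over 1.5 times in 3 settings: 728 on the deposited scale (165 higher, 563 lower), 745 with a 2-fold requirement (368 and 377) and 675 with the fluidics station as a block (334 and 341), a fit that compares the deletion arrays with 1 wild-type array. On the deposited scale the median SE of a tested probe set was 0.41, against 0.20. The median log2 change of all tested probe sets was also lower there, at -0.265 against -0.01, and more rises than falls lost their call. The median size of the change over the 2187, which ignores its sign, was 0.91 there, against 0.85. With the block the median SE was 0.28 and the median size 0.85, so precision fell while the typical size of a change did not. With the arrays scaled to one median the balance tipped the other way (1258 higher, 966 lower). The 2-fold requirement drops calls by construction. Leaving out each array in turn gave 1500 to 1964 called probe sets. With the dimmest 50% left out CBC2 itself was not tested, so no value could be given; in the other settings its log2 change ran from -4.90, where the floor was raised, to -6.77. Of 15 called lists, 0 were called with an estimated correlation and 23 of 30 by fry, which tests whether a list moves and not whether it moves more than other genes. Every called list kept the sign of its median in all 19 settings, though Gcn4, heat shock, hexose, Yap1 and pheromone lists lost their call in some.

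The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.23, -0.09 and 0.08. With the replicate block 1911 probe sets were called (955 higher, 956 lower).

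Of 134 named genes, 64 kept call and direction in each of the 19 settings that tested them. The direction of 2 genes that were not called reversed: SPO11 went to -0.039 on the deposited scale and FKS1 to 0.16 with the arrays scaled to one median; the cause was not tested. Of genes named after their values were seen and not called, MF(ALPHA)1 went to 0.03 on the deposited scale and to 0.355 with the arrays scaled to one median, GAP1 to 0.28 with the arrays scaled to one median, and GLN1 to -0.11 with the station block and to -0.004 without deletion replicate 2. Low signal limits the dim genes: values under 8.25 have no order.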

Other observations

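The list of allantoin and nitrogen catabolite genes, the single genes of this part other than CBC2, DAL5, DAL1 and SPT14, the probe set without a gene name and the tests of the genes around CBC2 were chosen only after the values had been seen.

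Among genes for the use of poor nitrogen sources, a list drawn up after the falls of DAL5 and DAL1 had been seen, most fell. Of 34 tested genes of allantoin and nitrogen catabolism, 23 fell, 1, ASP1 (0.68), rose and 10 were not called (median log2 change -1.03, 24 when adjusted over the list alone, camera adjusted p = 1.36e-08 over the 30 fixed and 3 added lists). With an estimated correlation the adjusted p was 0.00672 over the 3 added lists alone and 0.0739 over all 33, so over all 33 the call is lost. The estimate itself was -0.002, under the preset 0.01, so correlation between genes does not explain this loss. Besides DAL5 and DAL1, the allantoin genes DAL2 (-1.78), DAL3 (-1.55), DAL7 (-1.51) and DAL4 (-1.42) fell, as did the urea permease gene DUR3 (-1.57), the proline permease gene PUT4, from 7167 ± 1774 to 3082 ± 710 (n = 3 each; log2 fold change -1.21, SE 0.21, adjusted p = 0.00283), and the regulator gene GAT1 (-1.06). The general amino acid permease gene GAP1 was at 6030 ± 482 and 5375 ± 317 (adjusted p = 0.313) and the glutamine synthetase gene GLN1 at 2866 ± 342 and 3058 ± 543 (adjusted p = 0.731). The list's median stayed between -1.14 and -0.74 in all 19 settings. The calls of ASP1 and PUT4 were lost with the fluidics station as a block (0.61 and -0.76, adjusted p = 0.114 and 0.0814), that of ASP1 also on the deposited scale (0.49, adjusted p = 0.474). Of the 2 genes not called, GLN1 turned to -0.11 with the block and to -0.004 without deletion replicate 2, and GAP1 to 0.28 with the arrays scaled to one median (adjusted p = 0.231).

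One probe set without a gene name in the tables used here was at the floor on all 3 wild-type arrays and at 9205 ± 684 on the 3 deletion arrays, at least 1114-fold higher (log2 fold change 10.12, adjusted p = 9.20e-11). What it detects is not known here, so it is not read as a change of a yeast transcript. Telomerase RNA, TLC1, rose by 1.79 and 1.72 on its 2 probe sets, and the RNase P RNA gene RPR1 by 0.94, a call lost on the deposited scale and with the station block (0.63 and 0.84, adjusted p = 0.349 and 0.0641). Tested probe sets of the ribosomal RNA repeat moved both ways. Of the probe sets named RDN37-1, 5 were higher by 0.73 to 4.16 and 1 was not called, the one named RDN18-1 was higher by 3.70, and the 2 named RDN25-1 were at 3.57 and -1.20, all 3 called. For 5S ribosomal RNA, the 2 probe sets named RDN5-1 were not called (0.002 and 0.27) and the one named RDN5-3 fell by 0.95 (adjusted p = 0.0347).

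Several genes beside CBC2 had lower values in the deletion strain, which might come from a local effect at the deleted locus. The 4 tested genes on each side had a median log2 change of -0.49, and 2.91% of 4989 such windows along the chromosomes were as low. Windows of 1, 2, 8 and 16 genes on each side were matched or passed by 16.3%, 7.3%, 49.5% and 29.8% of windows, so 1 window size of 5 lay in the lowest 5%. The window of 4 genes was set first and met that rule, and the rule was then rewritten to need all 5 sizes. The wider windows would dilute an effect on the nearest genes and do not count against one, and the windows of 1 and 2 genes did not reach the lowest 5%, so the explanation stays open. Normalisation between arrays does not account for the lower values: less the median of all tested probe sets, the median of the 8 genes was -0.48, and at its highest -0.44 under the other scalings. SPT14 had the largest fall of the 8 (-1.29, SE 0.15, adjusted p = 0.000372).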
